A study of Bos taurus with 18 samples.

How the data were processed

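Gene expression was measured in bovine cumulus cells from follicles that had coasted, that is, grown without FSH, for 20, 44, 68 or 92 h. Per the labels' protocols, total RNA was amplified in 2 rounds, labelled chemically with Cy3 or Cy5 and hybridised to Agilent slides. Each of the 18 arrays held 20 h RNA in one channel and 44, 68 or 92 h RNA in the other. The labels give 3 biological replicates in each dye orientation with the same numbers. Arrays of one comparison and number in opposite orientations were taken as a technical dye swap of the same extracts, a reading that the labels do not state outright. Per the file headers, the deposited scanner tables hold the mean intensity of each spot and of its local background in both channels, not corrected and not normalized. The scanner, image software and the authors' own processing are not given in the sources used here. The deposited value table of the series holds a log2 ratio per probe and array. Its scale and direction were found by setting each column against the scanner values of its own array. It follows Cy5 over Cy3 with r from 0.73 to 0.87 and a slope from 0.96 to 1.15 on the log2 scale, with column medians from -0.04 to 0.02, and its background correction and normalization stay unknown. It served only as an alternative.

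Each array had 45220 spots, of which 43794 were gene probes and 153 negative controls, and between 2 and 24 spots per array were marked as ignored and left out. Raw median intensities ranged from 129 to 312 in Cy3 and from 102 to 257 in Cy5. Background was corrected with normexp (offset 50) on all spots, and each array was normalized by loess with control spots at weight 0. Ratios were turned to coasted over 20 h, and the 2 orientations of a replicate were averaged, which cancels a dye effect and leaves 9 values, 3 per comparison. A probe counted as above background when its signal over local background exceeded the mean plus 2 SD of the negative controls. It was kept when this held in the channel of at least 1 of the 4 coasting times on at least 50% of the arrays, which left 27381 probes. Dim probes have compressed ratios, and loess assumes that most genes of like brightness do not change, so a shift of most genes would be hidden. Of the 43794 probes, 21790 had 1 gene symbol in the platform annotation, 22004 had none and 0 had several. Symbols were current for 20025 probes, updated for 1524 and kept unmatched for 241. Where a gene had several probes, the brightest of those kept was used, leaving 11044 genes, and 12635 kept probes had no name and were only counted. Where a gene was not above background on any array of a group, its ratio is given as a lower bound: the bright group's mean over the dim group's mean of, per array, the higher of the lowest signal above background and the probe's own, from channels after loess and Aquantile scaling. No gene named as past the threshold at 92 h was such a gene.

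Differential expression was tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 1 coefficient per coasting time. The fit had 6 residual degrees of freedom and 1.13 prior degrees of freedom. It pooled the variance over the 3 longer times and treated all values as independent. Values of different times that share 20 h RNA would not be independent, so 6 may overstate the degrees of freedom. The p-values against 20 h do not allow for this. Tests were two-sided, with Benjamini-Hochberg adjustment over the 11044 genes and a threshold of 0.05. The 3 longer times were compared with 20 h directly and with each other through the 20 h RNA, and an F-test covered all 3. In all, 31 gene lists for cell cycle, metabolism, signalling, follicular function and markers of other cell types were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 186 tests. Of these tests 48 passed, and 0 passed with the correlation estimated from the residuals (smallest adjusted p = 0.274). Percentiles used 10000 random lists matched on mean intensity. The named genes are the 10 highest and 10 lowest ratios among genes past the threshold with 1 sign in the 3 replicates. Where fewer passed, those of smallest p up to 5 per direction are named and given as not past it. Differences between longer times have the 5 highest and lowest by the same rule and the F-test its 10 of smallest p. List members are drawn from the 4 of smallest p per list, and 16 genes of follicular function are always covered. The design, the tests, the lists, this rule and the alternatives were fixed before the data were examined, except where the text says that a choice came later.

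Replicate numbers do not mark shared animals in the labels. For 44 and 92 h, deviations from the time's mean correlated across genes between values of the same number with r of 0.36, 0.26 and 0.24, all above 0.1, so for that difference the numbers were also used as a block. For pairs with 68 h these correlations ranged from -0.35 to -0.03, so no separate fit with this block was made for differences with 68 h. One alternative fit used the number as a block over all 9 values. It therefore also paired the 68 h values by number, although these correlations give no ground for that. Slides were treated as batches in alternative fits only, and the main fit had no slide term. Slides 69 and 70 held only 92 h arrays, slide 71 only 68 h arrays, and slides 72 and 73 every 44 h array and 1 replicate of 68 h. Alternatives covered background correction, normalization, the filter, the probe per gene, the treatment of dye swaps, slide and replicate blocks, 1 dye orientation at a time, the variance prior, a fold threshold of 1.5, the authors' deposited ratios and leaving out each replicate. After the data were seen, the 3 sets into which the 20 h channels fall were added as a block for differences between the longer times, where the 20 h RNA of a set cancels. They were not used as a block against 20 h, where this would remove the spread of the 20 h samples from the error.

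The fit was tested on simulated data for 92 h against 20 h, with 11044 genes of which 200 were changed. It recovered 76 of 100 genes changed by a log2 ratio of 1 and 92 of 100 changed by 2, and called 20 unchanged genes. At 44 and 68 h, where nothing was changed, it called 0. A list shifted by -0.5 passed and 0 other lists did. Genes and values were drawn independently, without correlation inside lists or shared 20 h RNA. The simulation therefore cannot show how often lists or genes pass falsely in the real data. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.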

Results

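Cumulus cells are the somatic cells that surround the oocyte in the ovarian follicle and exchange metabolites with it. They were taken by ovum pick-up from 6 Holstein cows over 24 collections. Each cow received 6 doses of 40 mg of FSH, the hormone that drives follicle growth, at 12 h intervals over 3 days. FSH was then withheld for 20, 44, 68 or 92 h, a period called coasting. The series asks which cumulus transcripts accompany the gain of developmental competence by the oocyte before ovulation. Per the labels, the follicles measured 3 to 5 mm at 20 h, 6 to 8 mm at 44 and 68 h and more than 8 mm at 92 h, so coasting time and follicle size moved together. RNA from 44, 68 or 92 h was hybridised directly against RNA from 20 h on 18 dual-channel arrays, with 3 replicates per comparison and 2 dye orientations per replicate. Which cows went into which replicate is not stated, so the p-values measure the spread between these samples.

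Each array carried 43794 gene probes. The share of them above background ranged from 44.3 to 68.7% in the Cy3 channel and from 26.5 to 58.9% in the Cy5 channel. By time, the coasted channel had 50.9% ± 8.35 of probes above background at 44 h, 53.7% ± 14.2 at 68 h and 48.4% ± 8.75 at 92 h (SD, 6 arrays each), and the 20 h channel of the same arrays had 55.0% ± 11, 59.2% ± 5.84 and 52.2% ± 10.1. The 2 dye orientations of a replicate correlated across genes with r from 0.10 to 0.74 after both were turned to coasted over 20 h, and with r from 0.79 to 0.97 once the mean dye effect of each gene was removed. In 9 of 9 replicates this second r exceeded that with every other replicate of the same time. Log2 ratios of different replicates correlated across genes with r from 0.42 to 0.68 at 92 h, from 0.14 to 0.49 at 68 h and from -0.18 to 0.18 at 44 h. Genes are not independent replicates in these correlations, and the number of arrays limits the precision of all values.

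After 92 h of coasting, cumulus cells held less mRNA of genes for cell division, DNA replication and sterol synthesis than after 20 h, and more of a group led by VNN1, GATM and CEBPD. As lists, these 3 passed with a preset correlation between genes and not with an estimated one (adjusted p = 0.515, 0.559 and 0.559). Of 11044 genes tested with limma, 256 passed an adjusted p of 0.05, of which 137 rose and 119 fell. Their p-values rest on a variance pooled over times whose values may share 20 h RNA and were treated as independent. From the 3 values of 92 h alone 160 genes passed, 59 of them among the 256. All 256 had the same sign in the 3 replicates, 184 changed at least 1.5-fold and 81 at least 2-fold. At an unadjusted p under 0.05 there were 1991 genes, where 552 would pass by chance. Among genes of any size of change, 45.9% had the same sign in all 3 replicates, against 25% by chance. The count and its balance depended on processing. It was 459 genes without background correction (269 higher, 190 lower) and 68 with median centring (13 higher, 55 lower). With the replicate number as a block over all 9 values it was 117 (48 higher, 69 lower). For 44 and 92 h these numbers match the sets of 20 h channels, so this block may remove spread of the 20 h samples from the error. With a trended and robust variance prior 0 genes passed, and with the slide as a random block 4492 passed (consensus correlation -0.24), in a fit that counts the 18 arrays separately. Without 92 h replicate 1, 2 or 3 the count was 0, 12 or 65, without 44 h replicate 1, 2 or 3 it was 170, 526 or 498, and without 68 h replicate 1 or 3 it was 102 or 95.

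The largest rise at 92 h was in VNN1, a pantetheinase that releases cysteamine, with a log2 ratio of 3.76 ± 0.63 (SD, n = 3 here and below for single genes; adjusted p = 0.0208). GATM, the rate-limiting enzyme of creatine synthesis, rose by 2.63 ± 0.75 (adjusted p = 0.0389), and the transcription factor gene CEBPD rose by 2.50 ± 0.26 (adjusted p = 0.0311). APP, the amyloid precursor protein, rose by 2.20 ± 0.72, and ASNS, asparagine synthetase, by 1.91 ± 0.39. The remaining 5 of the 10 highest ratios were those of SIPA1L2 (1.84), PARM1 (1.78), LRRC17 (1.69), PDGFRA (1.66), a growth factor receptor, and TMEM37 (1.62), with adjusted p from 0.0228 to 0.0464. The deepest fall was in CRISPLD2, which encodes a secreted matrix protein, at -2.41 ± 0.76 (adjusted p = 0.0208). PBK, a mitotic kinase gene, CENPK, a kinetochore gene, and PGP, a phosphatase gene, fell to log2 ratios of -1.59, -1.52 and -1.47. PCLAF, whose product binds the replication clamp PCNA, fell with the least spread of these genes, -1.88 ± 0.01 (adjusted p = 0.0224).

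**Figure D1:**
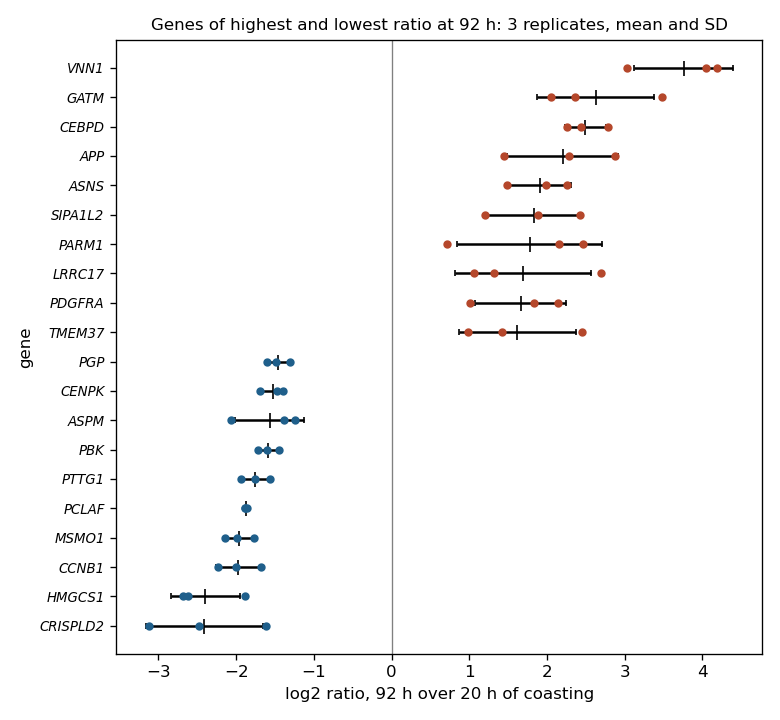
Log2 ratio of 92 h over 20 h of coasting (horizontal axis) for the 10 genes of highest and the 10 of lowest ratio among those past the threshold with one sign in all replicates; points are the 3 replicates, and the vertical tick and bar their mean and SD. VNN1 lies highest at 3.76 and CRISPLD2 lowest at -2.41.

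Genes of mitosis had the lowest median of the 31 lists at 92 h. Of 31 measured members of the mitosis and cell cycle list, 30 had a ratio below 0, with a median log2 ratio of -1.08. 10 of them fell when p was adjusted over all genes, 27 when adjusted over the list alone, and 0 rose. CCNB1, cyclin B1 of the mitotic kinase, fell to -1.97 ± 0.28 (adjusted p = 0.0291), PTTG1, the securin that restrains chromatid separation, to -1.75 ± 0.19 (adjusted p = 0.0208), and ASPM, a spindle pole gene, to -1.57 ± 0.44 (adjusted p = 0.0392). KIF11, a spindle motor, and CKS2, a subunit of cyclin-dependent kinases, fell to -1.41 and -1.06. CCNA2, cyclin A2, fell to -1.08, while a second probe of that gene read 0.02. Camera placed the list below other genes (adjusted p = 1.4e-19 with a preset correlation; adjusted p = 0.515 with an estimated correlation). None of 10000 random lists of matched size and intensity had a median as low (lowest -0.33). Random lists lack the correlation among the list's members, estimated at 0.34, and the spread between replicates. They set the list apart from unrelated genes only and do not test the effect of coasting.

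DNA replication genes moved in the same direction with a smaller median of -0.53 over 29 members, 27 of them below 0 (camera adjusted p = 1.9e-09; adjusted p = 0.559 with an estimated correlation). 4 fell and 1 rose, and adjusted over the list alone 17 fell and 1 rose. The replication clamp PCNA fell to -1.19 ± 0.16 (adjusted p = 0.0338), RRM2, a subunit of ribonucleotide reductase, to -1.42 ± 0.58 (adjusted p = 0.0465), and TYMS, thymidylate synthase, to -0.83 ± 0.18 (adjusted p = 0.0208), with another TYMS probe at 0.08. MCM2, a subunit of the replicative helicase, rose to 0.81 ± 0.17 by its brightest probe (adjusted p = 0.0291), but another MCM2 probe read -0.40.

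Sterol synthesis genes were lower at 92 h in 21 of 21 measured members, with a median log2 ratio of -0.73 (camera adjusted p = 8.6e-09; adjusted p = 0.559 with an estimated correlation). 3 fell over all genes and 9 adjusted over the list alone. HMGCS1, which makes HMG-CoA, fell to -2.39 ± 0.44 (adjusted p = 0.0170), the sterol oxidase MSMO1 to -1.97 ± 0.19 (adjusted p = 0.0416) and the farnesyl diphosphate synthase FDPS to -1.28 ± 0.13 (adjusted p = 0.0445). SQLE, squalene epoxidase, read -1.33 and did not pass (adjusted p = 0.0592). Glycolysis genes had a median of -0.68 over 21 members (camera adjusted p = 1.3e-04; adjusted p = 0.569 with an estimated correlation), of which 2 fell over all genes and 3 adjusted over the list alone. The 2 past over all genes were PGAM1, phosphoglycerate mutase, at -0.95 ± 0.16 and SLC16A1, a lactate and pyruvate transporter, at -1.13 ± 0.28. Of 23 fatty acid metabolism genes 4 fell, namely ACSL3 (-1.27), ACADL (-0.66), HADHB (-0.89) and the desaturase SCD (-0.95), while adjusted over the list alone 8 fell and 2 rose. That list's median was -0.25 (camera adjusted p = 0.00238; adjusted p = 0.515 with an estimated correlation).

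Lower medians at 92 h also came from the hypoxia list, -0.36 over 24 genes, and the oxidative phosphorylation list, -0.23 over 31 genes. Their camera adjusted p was 0.00178 and 0.00256, or adjusted p = 0.559 and 0.628 with an estimated correlation. Hypoxia did not pass with the coasted sample in Cy5 alone (camera adjusted p = 0.0753). Oxidative phosphorylation did not pass with it in Cy3 alone (camera adjusted p = 0.0824). In the hypoxia list 1 gene fell, EGLN3, an oxygen-sensing prolyl hydroxylase (-1.15 ± 0.41), and adjusted over the list alone 6 fell. In the oxidative phosphorylation list 0 genes passed over all genes and 0 over the list alone by limma.

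Immediate early genes, which respond within minutes to many signals, had a median log2 ratio of 0.72 at 92 h, with 20 of 22 members above 0 (camera adjusted p = 4.8e-05; adjusted p = 0.559 with an estimated correlation). The growth regulator MYC rose by 1.52 ± 0.33 (adjusted p = 0.0224) and DUSP6, a phosphatase of ERK kinases, by 0.73 ± 0.16 (adjusted p = 0.0311); these were the 2 that rose over all genes, and 3 rose adjusted over the list alone. Ribosomal protein genes had a median of 0.36 over 32 members (camera adjusted p = 2.3e-05; adjusted p = 0.274 with an estimated correlation). On the arrays with the coasted sample in Cy3 alone the median was 0.12 and did not pass (adjusted p = 0.150), with 0.10 to 0.19 on these arrays against 0.40 to 0.50 on those with it in Cy5. 1 of them rose, RPS7 by 0.69 ± 0.16, and 4 adjusted over the list alone. Lists with smaller upward medians were extracellular matrix (0.18, 20 genes, 0 past over all genes and 1 rose over the list alone), the IGF system (0.17, 11 genes) and apoptosis and atresia (0.17, 22 genes). Their camera adjusted p was 0.0322, 0.0344 and 0.0407, or adjusted p = 0.718, 0.559 and 0.559 with an estimated correlation. None of them passed in either dye orientation alone (camera adjusted p from 0.0635 to 0.177). The extracellular matrix medians were 0.092, 0.44 and -0.040 in replicates 1, 2 and 3, so 1 replicate carried that list and another had the opposite sign. In the IGF list, the binding protein gene IGFBP7 rose by 0.37 ± 0.05 and the insulin receptor INSR by 0.74 ± 0.08, and 4 rose over the list alone. In the apoptosis list 1 gene fell over all genes, CYCS, cytochrome c of the respiratory chain (-0.76 ± 0.29), and over the list alone 2 rose and 1 fell.

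**Figure D2:**
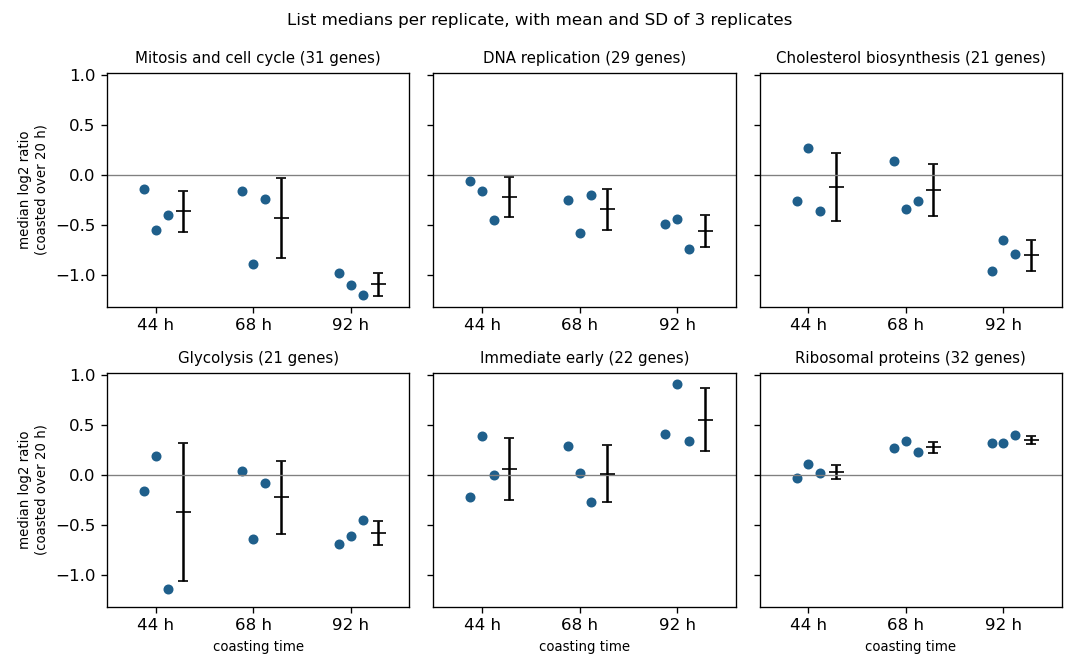
Median log2 ratio of coasted over 20 h (vertical axis) of 6 gene lists at 44, 68 and 92 h of coasting (horizontal axis). Points are the list medians of the 3 replicates in order of their number from left to right, and the bar their mean and SD. The mitosis list lies at -1.10 ± 0.11 at 92 h, against -0.40 ± 0.29 over the 6 values of 44 and 68 h together.

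Genes of follicular function gave few calls at 92 h. HSD3B1, which converts pregnenolone to progesterone, fell to -1.20 ± 0.02 (adjusted p = 0.0389), the single call in the steroidogenesis list of 17 genes, whose median of -0.18 did not pass (camera adjusted p = 0.0958). CYP19A1, the aromatase that makes oestradiol, read -1.08 ± 1.78 (adjusted p = 0.524), with -1.05, -2.88 and 0.69 in the replicates. INHBA, an inhibin and activin subunit, read -1.13 ± 1.74, with -0.62, -3.07 and 0.30 in the replicates. The FSH receptor FSHR (-0.30 ± 0.54), the cholesterol carrier STAR (0.00 ± 0.17) and cyclin CCND2 (0.57 ± 1.38) did not pass, with adjusted p of 0.628, 0.996 and 0.763. Among cumulus expansion genes, 0 of 21 passed by limma over all genes or over the list alone. HAS2, hyaluronan synthase, read 0.38 ± 0.48, TNFAIP6, a hyaluronan-binding protein, 1.80 ± 2.31 (replicates 1.06, 4.39 and -0.06), and GREM1, a BMP antagonist, -0.00 ± 0.04. ANGPT2, an angiopoietin, rose by 1.40 ± 0.37 (adjusted p = 0.0332), whereas the VEGF co-receptor NRP1 (1.92 ± 0.50, adjusted p = 0.0986) and the placental growth factor PGF (-1.93 ± 0.52, adjusted p = 0.134) did not pass. LHCGR, AREG, PTGS2 and IGFBP5 each had a probe, but none above background by the filter used.

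Lists of markers of other cell types did not pass at 92 h. The medians were 0.01 for 17 oocyte genes, 0.05 for 13 leukocyte genes, -0.01 for 10 endothelial genes, and within 0.01 of 0 for 17 theca and 7 erythrocyte genes (camera adjusted p from 0.0909 to 0.997). These lists were dim, with median log2 intensities from 7.97 to 8.15 against 10.66 for the mitosis list. Dim probes have compressed ratios, so medians near 0 cannot show that the share of other cells stayed the same. Single markers did rise, namely MYH11, a smooth muscle myosin in the theca list (1.47 ± 0.37, adjusted p = 0.0120; above background on 3 of 6 arrays at 20 h), PDGFRA of the same list, and CD68, a macrophage gene (0.93 ± 0.51, adjusted p = 0.0465). CXCR4, a chemokine receptor of the leukocyte list, read 1.43 ± 0.65 (adjusted p = 0.0504).

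The other lists did not pass at 92 h. Their median log2 ratios were 0.03 for amino acid and creatine metabolism, -0.02 for angiogenesis, -0.04 for antioxidant genes, -0.02 for cumulus expansion, 0.03 for gap junctions and transzonal projections, -0.14 for gonadotropin response and granulosa identity and -0.11 for heat shock. They were 0.09 for inflammation, -0.13 for interferon response, -0.02 for proteases and inhibitors, -0.00 for TGF-beta and BMP signalling, -0.08 for the unfolded protein response and 0.04 for Wnt and Notch genes. Camera adjusted p ranged from 0.107 for inflammation to 0.997 for cumulus expansion. Within them, DIAPH3, a formin of the gap junction list, fell to -0.91 ± 0.06, MT2A, a metallothionein, rose by 0.47 ± 0.22 (above background on 3 of 6 arrays at 20 h), and IL6ST, the shared receptor of interleukin-6 family cytokines, rose by 0.27 ± 0.07. Median, mean and camera direction differed in sign for the protease, TGF-beta, theca, oocyte and erythrocyte lists, all with medians within 0.02 of 0, and the mean was also opposite to the median for the angiogenesis, antioxidant and cumulus expansion lists.

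At 68 h no single gene passed, while the lists of cell division (lower) and ribosomal proteins (higher) passed with a preset correlation and not with an estimated one (adjusted p = 0.559 and 0.274). Both had the direction seen at 92 h, in comparisons that share the 20 h condition, and the ribosomal list lost the call when fitted on the arrays with the coasted sample in Cy3 alone (median -0.065, adjusted p = 0.981). By limma 0 of 11044 genes passed (smallest adjusted p = 0.0713), with 1217 at an unadjusted p under 0.05, 661 higher and 556 lower. In all 3 replicates the sign was the same in 42.9% of genes. The count was 201 with the slide as a fixed block over 12 arrays, in a fit that counts dye swaps as replicates. It was 4 with median centring, and 21, 15 or 11 without 44 h replicate 2, 44 h replicate 3 or 92 h replicate 2. Fits on 1 dye orientation alone, where the dye effect does not cancel, also gave calls. The higher genes of smallest p were GOLPH3L (0.51 ± 0.11), LOC100297334 (0.43), LOC784773 (0.51), CCN3 (0.61 ± 0.06), a matricellular protein, and LOC783399 (0.88). The lower ones were LRCH4 (-0.66), GCH1 (-0.88 ± 0.18), the first enzyme of tetrahydrobiopterin synthesis, the translesion polymerase POLH (-1.08 ± 0.15), the fatty acid activating enzyme ACSL3 (-1.01 ± 0.13) and VNN2 (-1.16 ± 0.42). Their adjusted p lay between 0.0713 and 0.0771.

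Of the 31 lists, 8 passed at 68 h with the preset correlation, 1 upward and 7 downward, and 0 with an estimated correlation. Mitosis genes had a median of -0.48 with 29 of 31 below 0 (camera adjusted p = 7.7e-08; adjusted p = 0.559 with an estimated correlation), led by KIF11 (-0.74 ± 0.47), NUSAP1 (-0.67), BUB1B (-0.66) and CENPF (-1.19 ± 0.15), with 0 members past by limma over all genes or over the list alone. DNA replication genes had a median of -0.33 (camera adjusted p = 3.2e-06; adjusted p = 0.559 with an estimated correlation), with 0 past over all genes and 3 that fell over the list alone; the lowest p belonged to RRM1 (-0.67), TYMS (-0.46), RFC4 (-0.79) and PCNA (-0.69). The replicate medians of the mitosis list were -0.16, -0.89 and -0.24, and without 68 h replicate 2 the median was -0.20 for mitosis and -0.18 for DNA replication. With the slide as a block these medians were -0.33 for mitosis and -0.26 for DNA replication. In slides 72 and 73 the single 68 h replicate read -0.24 and -0.20, and in slide 71 the other replicates read -0.51 and -0.44. Ribosomal protein genes had a median of 0.22, with 28 of 32 above 0 (camera adjusted p = 4.8e-05; adjusted p = 0.274 with an estimated correlation) and 2 that rose over the list alone. RPS7 (0.71 ± 0.01) and RPS15 (0.72 ± 0.13) were the members of smallest p. The list's median was -0.0050, 0.14 and -0.093 on the 3 arrays with the coasted sample in Cy3, and 0.42 to 0.52 on those with it in Cy5.

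The other lists past the threshold at 68 h were all lower. Genes of the unfolded protein response had a median of -0.26, 2 of which fell over the list alone, with the disulfide isomerases PDIA3 (-1.66 ± 0.51) and PDIA6 (-0.57 ± 0.16) of smallest p. Fatty acid metabolism had -0.12 (1 fell over the list alone), glycolysis -0.22, heat shock -0.20 and amino acid metabolism -0.10 (2 fell over the list alone). Camera adjusted p was 0.00469, 0.00504, 0.0261, 0.0322 and 0.0431 in this order, and adjusted p = 0.559, 0.515, 0.728, 0.559 and 0.628 with an estimated correlation. By limma 0 of their members passed over all genes. Fitted on 1 dye orientation alone, fatty acid metabolism, heat shock and amino acid metabolism passed in neither. The unfolded protein response passed with the coasted sample in Cy5 and not in Cy3 (camera adjusted p = 0.0218 and 0.169). Glycolysis passed in Cy3 and not in Cy5 (camera adjusted p = 0.0417 and 0.958). The median of glycolysis was 0.047, -0.64 and -0.074 in the replicates. The lowest was replicate 2, in the same set of 20 h channels as 44 h replicate 3, the lowest at 44 h (-1.14). If that set shares 20 h RNA, these 2 values are not independent. The arrays of 92 h replicate 3, also of that set, read -0.69 and -0.53, within the range of the other 92 h arrays. For the genes reported whatever their values, VNN1 read 0.91 ± 0.85, GATM 0.74 ± 0.47, NRP1 0.97 ± 0.68, CCND2 0.99 ± 1.31, INHBA 0.73 ± 1.10, CYP19A1 -0.40 ± 1.29, HSD3B1 -0.32 ± 0.27 and TNFAIP6 -0.27 ± 0.50. FSHR, STAR, HAS2 and GREM1 read -0.03, -0.04, -0.05 and 0.03, and the smallest adjusted p among these 12 genes was 0.536. In the coasted channel of 68 h replicate 2, 26.5% of probes were above background when it was labelled with Cy5, against 52.0 to 66.2% on the other 68 h arrays, and without that replicate the count of genes was also 0. The threshold from the negative controls was 281 in that channel, against 80 to 175 for Cy5 on the other 68 h arrays.

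At 44 h the replicates shared least with each other and again no gene passed. By limma 0 of 11044 genes passed (smallest adjusted p = 0.283), with 1057 at an unadjusted p under 0.05, 476 higher and 581 lower, and 25.6% of genes had the same sign in all replicates. The count was 4 with the slide as a fixed block over 12 arrays, in a fit that counts dye swaps as replicates. Higher genes of smallest p were CRIPT (0.62 ± 0.22), LOC504861 (0.54), GOLPH3L (0.30 ± 0.05), LINGO1 (0.66) and SNTB1 (0.23). Lower ones were MRPS27 (-0.63 ± 0.16), a mitochondrial ribosomal protein, SNRNP70 (-0.51), a spliceosomal protein, FKBP2 (-0.69), SDF2 (-0.49 ± 0.06) and NAP1L4 (-0.68), all with an adjusted p of 0.283. VNN1 read 0.63 ± 1.17, GATM 0.69 ± 1.19, NRP1 0.07 ± 1.40, CYP19A1 -0.70 ± 0.99, INHBA -0.52 ± 0.89, CCND2 -0.48 ± 1.14 and HSD3B1 -0.46 ± 0.62. FSHR read -0.43 ± 0.61, STAR 0.02, HAS2 -0.01, TNFAIP6 -0.15 and GREM1 0.01.

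Of the 31 lists, 6 passed at 44 h with the preset correlation, all downward, and 0 with an estimated correlation. Mitosis genes had a median of -0.43 with 30 of 31 below 0 (camera adjusted p = 2.8e-08; adjusted p = 0.559 with an estimated correlation). CCNB1 read -0.99 ± 0.59, AURKA, a mitotic kinase, -0.90 ± 0.90, BUB1B -0.52 and BIRC5, survivin, -1.10 ± 1.13. DNA replication genes had a median of -0.26 (camera adjusted p = 4.5e-06; adjusted p = 0.559 with an estimated correlation), with the helicase subunits MCM7 (-0.40 ± 0.20), MCM4 (-1.28 ± 1.07) and MCM3 (-0.98 ± 0.73) among the smallest p. With the slide as a block the medians were -0.49 and -0.31. Slides 72 and 73 held every 44 h array, so the fit within them repeats the main medians of -0.43 and -0.26 and is no separate check. The other lists were glycolysis (-0.47), the unfolded protein response (-0.23), oxidative phosphorylation (-0.28) and interferon response (-0.26). Camera adjusted p was 0.00292, 0.00292, 0.0149 and 0.0261, and adjusted p = 0.657, 0.559, 0.716 and 0.801 with an estimated correlation. By limma 0 of the members of these 6 lists passed over all genes or over the list alone. Without 44 h replicate 3 the median was -0.04 for glycolysis, where the list no longer passed, and -0.092 for DNA replication. Both lists had their lowest 68 h median in replicate 2, of the same set of 20 h channels (-0.64 and -0.58). The 2 times may therefore not be independent there. Glycolysis also did not pass on the arrays with the coasted sample in Cy5 alone (median -0.25, adjusted p = 0.416). The unfolded protein response, oxidative phosphorylation and interferon response passed in neither dye orientation alone (camera adjusted p from 0.0667 to 0.182). In replicates 1, 2 and 3 the medians were 0.088, -0.52 and -0.10 for oxidative phosphorylation and 0.035, -0.57 and -0.11 for interferon response, so 1 replicate carried each and another had the opposite sign. Replicate 2 of 44 h fell in the same set of 20 h channels as replicate 1 of 68 h. There the interferon median was -0.59, against 0.086 and 0.042 in the other 68 h replicates. For oxidative phosphorylation the 68 h medians were -0.16, -0.16 and 0.045 in replicates 1, 2 and 3.

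The longer times were also compared with each other through the 20 h RNA on each array. No single gene passed, while lists past the threshold between 92 h and both earlier times included those of cell division, sterol synthesis and immediate early genes. They passed with the preset correlation, and 0 of 31 lists passed in each comparison with an estimated one. By limma 0 genes passed between 68 h and 44 h, between 92 h and 68 h, between 92 h and 44 h, and among the 3 times by the F-test. At an unadjusted p under 0.05 there were 596, 656, 857 and 818 genes, and the smallest adjusted p was 0.50, 0.642, 0.126 and 0.333. Without 92 h replicate 3, the counts between 92 h and 68 h and between 92 h and 44 h were 1 and 3. These fits leave aside that the 20 h channels fell into 3 sets with 1 replicate of each time. With the set as a block, a choice made after the data were seen, the 4 counts were also 0 (smallest adjusted p = 0.329, 0.410, 0.181 and 0.315), with 897, 1027, 1226 and 1202 genes at an unadjusted p under 0.05. The mitosis list was lower at 92 h by a median of -0.57 than at 68 h (camera adjusted p = 3.8e-11; adjusted p = 0.559 with an estimated correlation) and of -0.58 than at 44 h (camera adjusted p = 4.4e-10; adjusted p = 0.559 with an estimated correlation). The sterol synthesis list differed by -0.44 and -0.53, with 21 and 19 of 21 members lower (camera adjusted p = 1.6e-06 and 3.5e-06; adjusted p = 0.559 for both with an estimated correlation). The immediate early list differed by 0.44 and 0.70 (camera adjusted p = 8.1e-05 and 4.8e-05; adjusted p = 0.559 for both with an estimated correlation). Ribosomal protein genes were higher at 68 h than at 44 h by 0.27 (camera adjusted p = 0.00289; adjusted p = 0.472 with an estimated correlation) and at 92 h than at 44 h by 0.30 (camera adjusted p = 1.8e-04; adjusted p = 0.274 with an estimated correlation). On the arrays with the coasted sample in Cy3 alone the first difference was 0.11 and did not pass (adjusted p = 0.605), against 0.33 in Cy5 alone, while the second passed in each orientation (0.31 and 0.34).

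Among single genes, MYH11 was higher at 92 h than at 68 h by 1.04 (SE 0.18) and than at 44 h by 1.51 (SE 0.18), with adjusted p of 0.642 and 0.126. The other higher genes of smallest p between 92 h and 68 h were SNU13 (0.55), DDO (1.26), KANSL2 (0.74) and PAM (1.14), and the lower ones PDHB (-0.33), a subunit of pyruvate dehydrogenase, ANAPC13 (-0.79), the citrate synthase CS (-0.41), the proteasome subunit PSMA6 (-0.40) and LOC783399 (-0.81). Between 92 h and 44 h they were IGFBP7 (0.67), PRCP (0.67), FANK1 (0.37) and PLOD3 (0.58), and on the lower side ZDHHC21 (-0.73), PDHB (-0.44), PSMA6 (-0.54) and the centromere genes CENPM (-0.92) and CENPS (-1.10). Between 68 h and 44 h they were RPL29 (0.95), MMS19 (0.74), ARHGAP1 (0.59), LOC100295855 (0.60) and ROBO1 (0.53), and WARS1 (-0.44), BCOR (-0.62), HOXB2 (-0.43), NSF (-0.35) and TMPRSS3 (-0.41) on the lower side. The F-test ranked PDHB, IGFBP7, ZDHHC21, MYH11, PRCP, SNU13, PSMA6, DDO, FANK1 and PLOD3 first, all at an adjusted p of 0.333.

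Of the 256 genes called at 92 h, 248 (96.9%) had the same sign at 68 h and 190 (74.2%) at 44 h, and 0 were also called there. These shares measure no shared response by themselves, since the comparisons share the 20 h condition and the genes were taken for large ratios. In 100 simulations of unchanged groups sharing 20 h samples, the 256 genes of smallest p had the same sign in 85.9% (80.9 to 90.6%). Log2 ratios over 20 h correlated across genes with r = 0.54 between 68 and 92 h, 0.50 between 44 and 92 h and 0.40 between 44 and 68 h, against a mean r of 0.50 in the simulations for each pair of times. The same sign was seen in 67.6, 62.9 and 60.9% of all genes, against 66.7% in the simulations. The covariance was 0.0502, 0.0476 and 0.0253 against a simulated 0.0232, 0.0231 and 0.0231, a difference of 0.0270, 0.0245 and 0.0021. Part of any excess may come from the shared 20 h samples, since 3 replicates cannot be divided into parts of at least 2. One replicate of the earlier time was also set against the mean of the 2 at the later time that belong to other sets of 20 h channels, a choice made after the data were seen. Over the 3 such choices r was 0.051 to 0.40 (mean 0.21) for 68 and 92 h, 0.12 to 0.26 (mean 0.19) for 44 and 92 h and -0.072 to 0.28 (mean 0.16) for 44 and 68 h. The covariance was 0.0325 ± 0.0345, 0.0346 ± 0.0252 and 0.0163 ± 0.0272 (SD over the 3 choices, which have replicates in common).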

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

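The tests of the 20 h channels and of the lower mitosis list were chosen only after these results were seen, as were the block by replicate number for 44 and 92 h, the block by set and the splits within or along the sets; the other counts over splits of the replicates were planned.

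Differences between the longer times were past the threshold for 22 list comparisons by camera with the preset correlation and for 0 with an estimated one. Between 92 and 68 h, the median differences of lower lists were -0.57 for mitosis, -0.44 for sterol synthesis, -0.41 for glycolysis, -0.29 for oxidative phosphorylation, -0.18 for DNA replication and -0.10 for gonadotropin response. Those of higher lists were 0.44 for immediate early genes, 0.40 for the IGF system, 0.27 for extracellular matrix, 0.17 for apoptosis, 0.13 for amino acid metabolism and 0.057 for inflammation. Between 92 and 44 h they were -0.58 for mitosis, -0.53 for sterol synthesis, -0.23 for DNA replication, -0.12 for hypoxia, -0.026 for fatty acid metabolism, 0.70 for immediate early genes, 0.31 for apoptosis, 0.30 for ribosomal proteins and 0.29 for the IGF system. With the replicate number as a block over 44 and 92 h alone, 7 of these 9 still passed, while fatty acid metabolism and the IGF system did not (adjusted p = 0.0592 and 0.0978). Between 68 and 44 h, ribosomal protein genes differed by 0.27. With the coasted sample in Cy3 alone, mitosis, sterol synthesis and immediate early genes kept the call between 92 and 68 h. The other lists named for that comparison lost it (camera adjusted p from 0.0521 to 0.207). Between 92 and 44 h, hypoxia passed in neither orientation alone and the IGF system in Cy5 alone. The ribosomal difference between 68 and 44 h did not pass in Cy3 alone. With the set of 20 h channels as a block, over 93 tests, 17 of the 22 still passed and 1 other did, again 0 with an estimated correlation. The 5 that did not were extracellular matrix, the IGF system and inflammation between 92 and 68 h (adjusted p = 0.0759, 0.0992 and 0.0819) and fatty acid metabolism and the IGF system between 92 and 44 h (adjusted p = 0.0759 and 0.0992).

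The mitosis list was lower at 92 h, with replicate medians of -1.10 ± 0.11 (SD, n = 3) against -0.40 ± 0.29 over the 6 values of 44 and 68 h. The list was picked from 31 and the time set apart from 3, so each split of the 9 values into 3 parts was counted by its largest difference of 1 part from the others over all 31 lists. A difference in size of at least that of -0.70 came from 10 of 280 splits (highest other 0.68; exact two-sided permutation p = 0.0357), those that keep the 92 h values together. Values that share 20 h RNA are not independent, and of the 36 splits with 1 value of each set in each part 4 gave as much (highest other 0.63); these splits are too few for a share under 0.05, since each part recurs in 4 of them. Whether chance is excluded therefore stays open. The tables argue against intensity-dependent normalization and a single replicate as the cause. The median nearest 0 was -1.08 over the background and normalization settings and -1.09 with 1 replicate of 92 h left out. The -1.08 equals the main value, which quantile scaling keeps by construction, so no other setting brought the median nearer 0. Every setting centres each array on most genes, so a shift of most genes was not tested. Oocyte RNA in the 20 h samples stays open. The 6 oocyte markers above background in the 20 h channel of all arrays had a median of 0.0070 ± 0.36, but only 1 of them, UCHL1 at -0.82, was as bright as the median of the mitosis list. The next brightest, KPNA7 and TLE6, read -0.010 and 0.13, FBXO15 read -0.33, and dim probes have compressed ratios. Slides 69 and 70 held only 92 h arrays. The list's medians were -0.86 to -1.26 on slide 69, with 92 h in Cy3, and -1.07 to -1.27 on slide 70, with 92 h in Cy5. A dye effect common to both slides would change sign between them, so these values argue against it. Slide effects that differ between these slides or that scale the ratios cannot be told apart from 92 h. Follicle size rose with coasting time. A lower share of dividing cumulus cells at 92 h remains a candidate explanation, untested here, beside the larger follicles and such remaining slide effects.

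The 20 h channels of the 9 replicates may fall into 3 sets, each with 1 replicate of each comparison. In the 2731 genes not used to form the sets, r between 20 h channels was taken after removing each gene's mean over the arrays of a dye orientation. It ranged from 0.711 to 0.940 in the 9 pairs within a set and from -0.71 to -0.20 between sets. Removing the mean pushes r between sets below 0, so the negative values do not show opposite expression. The high r within sets is what 20 h RNA shared between comparisons would give. A shared slide is argued against, since 20 h channels of a set on different slides still correlated with r of at least 0.556. Of the 9 pairs, 3 carried the same replicate number, and whether a set is 1 extract or 1 collection stays open.

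In the coasted channel of 68 h replicate 2 labelled with Cy5, 26.5% of probes were above background, far from the 52.0 to 66.2% of the other 5 arrays. Its Cy5 threshold from the negative controls was 281, against 80 to 175 on the other 68 h arrays. Its raw Cy5 median of 230 was the highest of the 68 h arrays, so the low share went with a high threshold and not with dim signal. This array was the only such one in 33 groups of 6 tested, and chance marks about 1 group in 20.

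Probes without a gene name, which were tested and counted but not described, included 115 past the threshold at 92 h, 69 higher and 46 lower, out of 355 among all 27381 probes tested together.

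Other splits of the replicates bear on the counts as follows. Turning the sign of replicates gives 4 arrangements per time, too few for a share under 0.05: at 92 h the real one gave 256 genes and the highest other 0 (1 of 4 as large), and at 44 and 68 h real and highest other were 0 (4 of 4). For each difference of 2 longer times, 10 splits are too few as well: the real count was 0 and the highest other 0 for 68 and 44 h, 0 for 92 and 68 h and 1 for 92 and 44 h (10 of 10 as large). For the F-test the real count was 0, which every split matches (100 of 100 drawn), so the splits cannot decide about chance there. Of them 11 gave more than 0, the highest 81 genes, which points to a structure of the samples other than coasting time. In that split 1 part was exactly 1 of the 3 sets of 20 h channels. Of the 13 drawn splits with a set as 1 part, 10 gave more than 0 genes, and of the 87 others 1 did (highest 4). With the set as a block, the F-test count was again 0 in the real split and in all others that exchange times within sets (36 of 36 as large, highest other 0), which decides nothing about chance either. For each difference of 2 times 4 such splits are too few for a share under 0.05 (4 of 4, real and highest other 0).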

How the results depend on the processing

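The fit within the slides that hold both 44 and 68 h, the block over 44 and 92 h alone, the block by set of 20 h channels and the correlation over different sets were chosen only after the data were seen. Under the alternatives run, the 48 results of named genes past the threshold at 92 h kept their direction and stayed past it in 836 of 1242 cases and lost the call in 406. The 83 named results not past it were within 1 SD in 1957 of 2254 cases, passed in 202 and moved further in 95. The 12 leading list results kept call and direction in 224 of 240 cases, lost the call in 15 and reversed in 1. The causes below were not tested unless stated. Quantile scaling of mean intensities leaves ratios as they are by construction. Dim signal limits the genes: 5482 stayed under the strict filter.

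Genes changed at 92 h numbered 459 without background correction (269 higher, 190 lower), 68 with median centring (13 higher, 55 lower, against 137 and 119), 1489 with the coasted sample in Cy3 only, 160 from that time's own 3 values, 0 with trended and robust variance, and 825 at an unadjusted p with 1.5-fold. At 68 h median centring gave 4, Cy5 only 62, Cy3 only 1822 and the unadjusted rule 251. At 44 h Cy3 only gave 92 and the unadjusted rule 325. Against 20 h, fits on 1 dye orientation do not cancel the dye effect of each gene (SD 0.21 over genes). Their gene and list results therefore also hold dye bias. The unadjusted rule gave 240, 309 and 377 for 68 and 44 h, 92 and 68 h, and 92 and 44 h. Of the 256 genes, 169 were also among the 290 from the authors' ratios.

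Treating 18 arrays as separate, which counts dye swaps as replicates, gave 1033, 1158 and 2480 genes at 44, 68 and 92 h, 359, 349 and 663 for these differences and 991 for the F-test. With the replicate pair as a random block (correlation 0.83) the counts were 169, 293 and 1279, then 21 for 92 and 68 h, 150 for 92 and 44 h and 71 for the F-test. With the slide as a random block (correlation -0.24) they were 4185, 4952 and 4492, 2573, 2328, 3309 and 4422, and with it fixed over 12 arrays 4 at 44 h and 201 at 68 h. Both slide fits also count dye swaps as replicates.

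With the replicate number as a block over all 9 values, 117 genes passed at 92 h (48 higher, 69 lower, 91 of the 256), and it changed no other count from 0. For 44 and 92 h, values of the same number fell in the same set of 20 h channels, while the 68 h numbers did not follow the sets. Like the set, this block may therefore remove spread of the 20 h samples from the error against 20 h. Over 44 and 92 h alone the block also gave 0 genes, with 886 at an unadjusted p. With the set of 20 h channels as a block, used for differences between the longer times alone, these 3 counts and the F-test stayed at 0. Same-number deviations did not correlate in all pairs (-0.35 to 0.36).

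List calls went from 48 to 0 with an estimated correlation and to 25 with Cy3 only and 35 with Cy5 only. Of the 48, 20 held in each dye orientation alone and 11 in neither, in a count added after the data were seen. Glycolysis at 44 h lost the call with Cy5 only (from -0.47 to -0.25, adjusted p = 0.416) and without 44 h replicate 3 (-0.039). With Cy3 only, the ribosomal list at 92 h fell to 0.12 and lost the call (adjusted p = 0.150). The ribosomal list at 68 h reversed to -0.065 with Cy3 only (adjusted p = 0.981). With no shared replicate number, r between times fell from 0.54 to 0.27 for 68 and 92 h and from 0.50 to 0.12 for 44 and 92 h, while it rose from 0.40 to 0.52 for 44 and 68 h. By the sets of 20 h channels only the 0.12 is free of shared 20 h RNA, since numbers do not mark the sets for 68 h. Between different sets the mean r was 0.21 for 68 and 92 h, 0.19 for 44 and 92 h and 0.16 for 44 and 68 h. Without 68 h replicate 2 the 68 h medians went from -0.48 to -0.20 for mitosis and from -0.33 to -0.18 for DNA replication, and without 44 h replicate 3 the 44 h median of DNA replication from -0.26 to -0.092, all still past the threshold. Leaving out 1 replicate gave 0 to 526 genes at 92 h, 0 to 21 at 68 h, 0 to 1 for 92 and 68 h and 0 to 3 for 92 and 44 h.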

Other observations

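Some signalling and matrix genes had high ratios at 92 h without passing over all genes. In the TGF-beta and BMP list, adjusted over the list alone, 3 of 27 genes rose and 0 fell, and over all genes 0 passed by limma. Its members of smallest p were the activin receptor ACVR2A (0.32 ± 0.08, SD, n = 3), the BMP antagonist NOG (not above background on any 20 h array of the comparison, at least 2.00-fold higher at 92 h), the BMP receptor BMPR1B (0.75 ± 0.43) and TGFBR3, betaglycan (1.23 ± 0.46), with adjusted p from 0.0612 to 0.118. In the extracellular matrix list, LAMB1 was likewise not above background at 20 h and at least 1.64-fold higher at 92 h, where 5 of 6 arrays measured it, THBS1 read 1.93 ± 1.20 and POSTN read 1.37 ± 1.40, with adjusted p of 0.0580, 0.113 and 0.161. CLU, clusterin, a secreted chaperone in the apoptosis list, read 2.15 ± 1.56 (adjusted p = 0.0782).

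TNFAIP6, CYP19A1 and INHBA varied widely between replicates at 92 h, each with its most extreme value in replicate 2. TNFAIP6 read 1.06, 4.39 and -0.06 in replicates 1, 2 and 3, CYP19A1 -1.05, -2.88 and 0.69 and INHBA -0.62, -3.07 and 0.30. These genes were picked out after their values were seen, and no explanation was tested.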
